A study of Rattus norvegicus with 48 samples.

How the data were processed

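PolyA-selected RNA from the subcutaneous and visceral fat of 24 rats was sequenced as 50-nt single-end reads, per the labels' protocols, which also state that only RNA with an integrity number over 9 was used and an average of 21 M reads. The deposited table holds estimated counts per gene, as whole numbers, for 23481 Ensembl gene IDs in 48 libraries; Salmon 1.4.0 and the genome build rn6 are named in the submitters' processing notes. The annotation release and how transcripts were summed to genes are not given in the sources used here. No gene coordinates were used. The columns were matched to samples through the library names in the labels, where AM and PM stand for the early and late groups. No column was left without a sample and no row lacked a gene ID.

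The IDs could not be paired with symbols: of the table of rat gene names at hand, 0 rows carried an Ensembl ID and 0 of the IDs matched. The 27 gene lists fixed before the data were examined, their tests, and the genes that were to be named in every case were therefore not analysed here. The rule for named genes asked, for each comparison, for the 6 largest rises and the 6 largest falls (10 and 10 for the depots), with members of the gene lists, among called genes with a symbol and a mean of at least 5 CPM in a compared group. Without symbols it was reduced to the 2 largest rises and the 2 largest falls of the SAT phase comparison in sedentary rats, and these IDs were followed through all groups; genes of other comparisons are described by their values. This adaptation was made after the table was seen.

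Counts were read as deposited, rounded to whole numbers (they already were), and tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, a quasi-likelihood fit of the 4 groups of a depot (24 libraries) or of the 8 groups (48 libraries), and contrasts with Benjamini-Hochberg adjustment at 0.05. The filter kept 14372 genes in SAT and 13883 in VAT, with 99.9% of the counts in each. The common biological coefficient of variation was 36% in SAT and 21.1% in VAT. Standard errors of log2 fold changes are the fold change over the square root of its F value. CPM values use the TMM library sizes, and log2 CPM for principal components used a prior count of 2. No count in any library was found for 3075 of the genes. Intervals and floors from counts cover counting error only; the lowest library allows 0.228 CPM for a gene with 0 counts (3 counts of the total). Overlaps and correlations are across genes, which are not independent replicates.

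Replicates are separate rats, per the labels. All 120 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.51 to 583. No library thus appeared to be a copy of another of its group. Pairs from different groups were not compared in this way. The replicate numbers pair the depots: the labels describe 6 rats per group with both depots, and 35 genes had deviations from the group mean that correlated over 0.8 between a rat's depots, against at most 1 in 100 permutations of the rats. With these genes chosen without the rat in question, 23 of 24 rats matched their own other depot, where 4 would by chance; late exercise rat 4, whose SAT library is atypical, did not. Within a depot, replicate numbers of different groups name different rats.

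The fits were tested on simulated counts with the means, library sizes and dispersions of the real libraries and 200 changed genes. Each gene had the same dispersion in all 4 groups and was drawn independently of the others, so atypical libraries were not simulated. For the SAT early exercise comparison (14234 genes) edgeR recovered 80.3% of the changes of 4-fold and called 7 unchanged genes; for the VAT early exercise comparison (13805 genes) it recovered 95.5% and called 10.

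Alternatives fixed before the data were examined were DESeq2 size factors, no filter beyond 1 count, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, a fit of only the 2 groups compared, a replicate block and leaving out each library. Added after seeing the data were leaving out the atypical libraries, the number of detected genes as a covariate, the first principal component as a covariate, correlations of left-out fits over the genes first tested, and the depot by phase interaction. A library was called atypical where its median Spearman correlation lay over 5 median absolute deviations below that of its depot. Other splits of the samples into groups of the same sizes were drawn, 100 for each comparison including the real split.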

Results

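RNA was measured in 2 fat depots of male adolescent rats that were either sedentary or had been exercised at a fixed time of the active phase, which in rats is the dark part of the day. The depots were subcutaneous adipose tissue (SAT) and visceral adipose tissue (VAT). Sessions and tissue collection belonged either to the early active phase (zeitgeber time, the hours after lights on, of 13) or to the late active phase (zeitgeber time of 23). This gave the groups early control (EAC), early exercise (EAE), late control (LAC) and late exercise (LAE), with 6 rats in each. Tissue was taken on postnatal day 61, 24 h after the last session, and both depots of the 24 rats were sequenced, for 48 libraries. Each library held between 13163675 and 17890033 estimated counts, with a median of 15576425, so that 1 count at the lowest total was worth 0.076 CPM (the count scaled by the library total). The table names genes by Ensembl ID and does not pair the IDs with symbols, so the results below are given as sets of genes and their sizes, with 4 IDs followed through all groups.

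In VAT 10 of the 12 early libraries lay above all 12 late libraries on the second principal component, and the other 2 lay far out on the first. The first VAT component also largely followed phase. Early libraries lay at -4.679 or higher on it, and late libraries at -6.72 or lower except late control replicate 4 at 2.086. In SAT neither of the first 2 components parted early from late libraries. These components held 39.8% and 12.6% of the variance in SAT and 20.5% and 15.8% in VAT. A score over 50 genes called for phase in sedentary rats of the other depot placed every library of SAT and of VAT on the side of its labelled phase, with the depots taken from the same rats. SAT early libraries scored between -0.975 and -0.534 and SAT late libraries between 0.352 and 1.05 on the log2 scale.

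**Figure D1:**
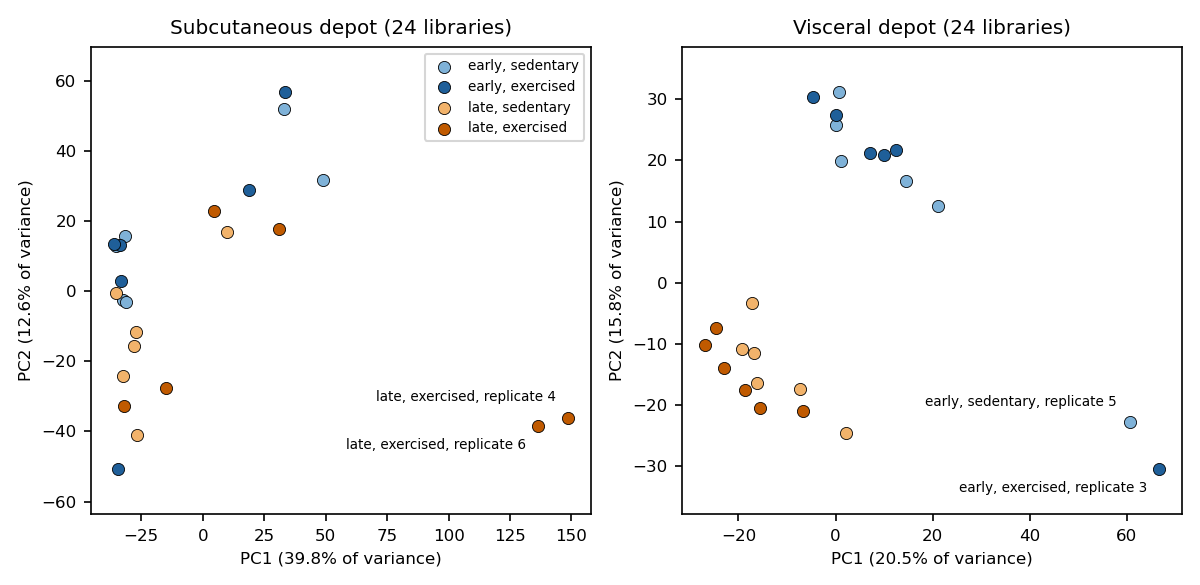
Principal components of log2 CPM in SAT (left) and VAT (right), 1 point per library, coloured by group, with the share of variance on each axis. Late exercise replicates 4 and 6 in SAT and early control replicate 5 and early exercise replicate 3 in VAT lie apart from the other libraries on the first component.

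In all, 4 libraries stood apart from the rest of their depot by a margin of more than 5 median absolute deviations in their median rank correlation with the other libraries. In SAT these were late exercise replicate 4 (median Spearman correlation 0.828) and late exercise replicate 6 (0.846), against 0.956 to 0.98 for the other 22 libraries. They carried 879 and 881 genes over 4-fold above the depot median, against 26 to 319 in the others. In VAT they were early exercise replicate 3 (0.95, 348 genes) and early control replicate 5 (0.958, 285 genes), against 0.976 to 0.984 and 20 to 79 genes in the other 22. The comparisons were therefore also fitted without the atypical libraries, a choice made after seeing the data.

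**Figure D2:**
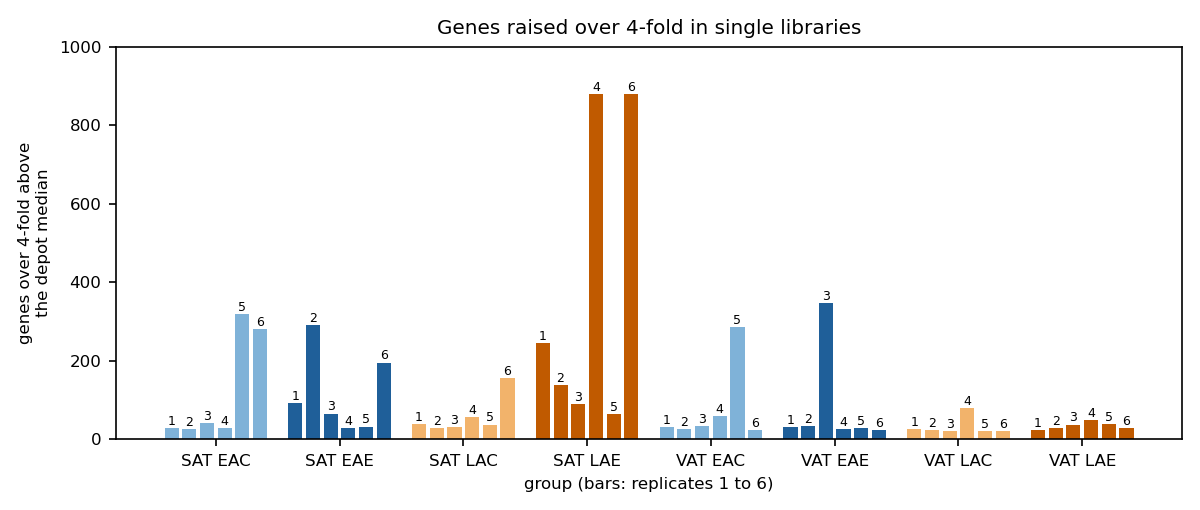
Number of genes over 4-fold above the depot median in each library, with 1 bar per library, labelled with its replicate number and grouped by depot and condition. SAT late exercise replicates 4 and 6 reach 879 and 881 genes and VAT early exercise replicate 3 and early control replicate 5 reach 348 and 285.

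The effect of phase without exercise was read from sedentary rats, comparing late with early control. These were different rats, so any difference in handling or processing between the groups cannot be told apart from the time of collection. The gene ENSRNOG00000013408 rose in SAT from 2.04 ± 0.992 CPM early to 61.5 ± 8.84 CPM late (SD, n = 6), a 30.1-fold change (log2 4.91 ± 0.323 SE, adjusted p = 4.90e-10, edgeR). In VAT it rose from 2.47 ± 0.917 to 60.7 ± 12.7 CPM, which was 24.7-fold (adjusted p = 9.31e-14, edgeR). ENSRNOG00000014448 rose 15.8-fold in either depot, from 3.78 ± 1.73 to 59.6 ± 4.55 CPM in SAT and from 2.9 ± 1.62 to 46.3 ± 2.21 CPM in VAT. In the opposite direction, ENSRNOG00000009329 fell from 82.2 ± 27.2 to 4.2 ± 1.69 CPM in SAT and from 68.6 ± 24.9 to 2.62 ± 0.488 CPM in VAT, falls of 19.7-fold and 26.1-fold. ENSRNOG00000042717 fell 30-fold in SAT, from 10.1 ± 3.77 to 0.33 ± 0.193 CPM, and 23.7-fold in VAT, from 9.23 ± 4.5 to 0.382 ± 0.102 CPM. For each of the 4 IDs, all 6 late libraries lay beyond all 6 early libraries of the same depot and activity.

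**Figure D3:**
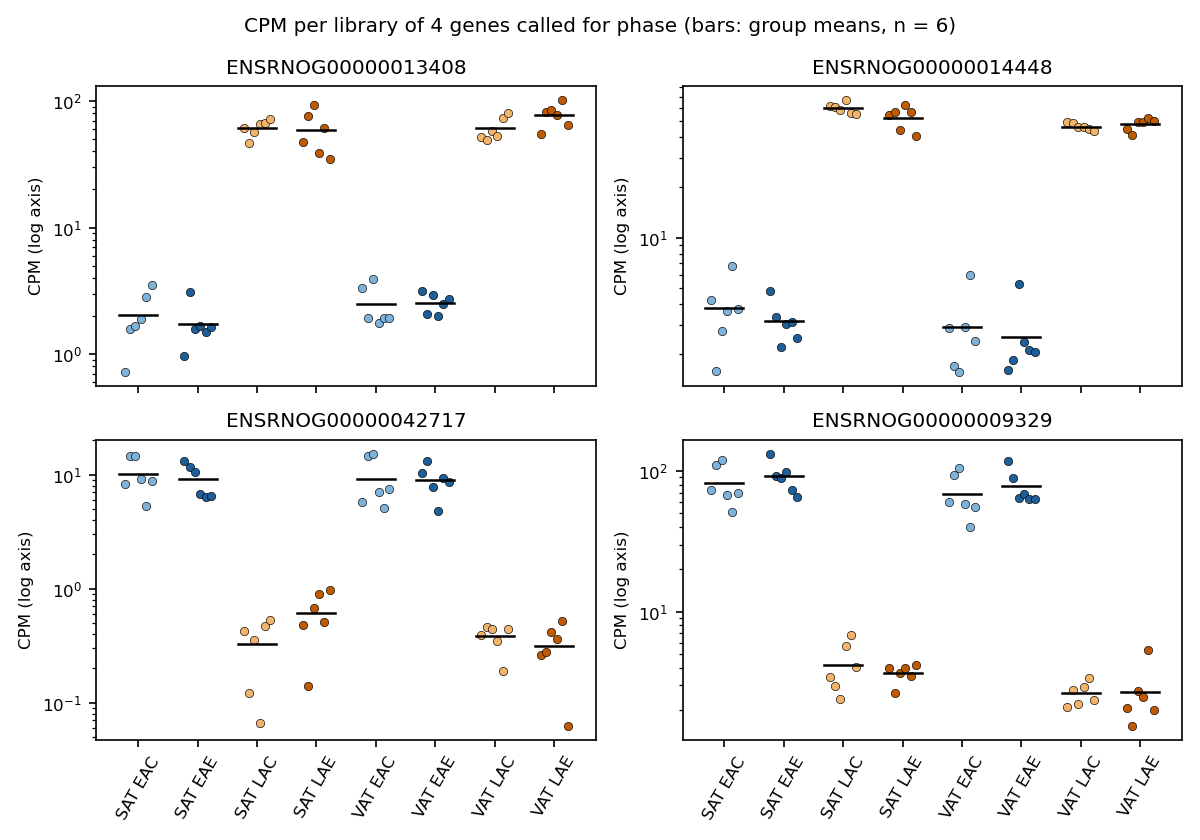
CPM (log axis) of 4 genes called for phase in every group of both depots, with 1 point per library and a black line at the group mean (n = 6). ENSRNOG00000013408 and ENSRNOG00000014448 are high in the late groups and ENSRNOG00000042717 and ENSRNOG00000009329 in the early groups, with or without exercise.

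Across the genome, 463 of 14372 tested genes differed between late and early sedentary rats in SAT, of which 220 were higher late and 243 lower. In VAT 1575 of 13883 did, 748 higher and 827 lower (edgeR's quasi-likelihood test, adjusted p under 0.05). Changes over 2-fold made up 130 of the SAT calls and 241 of the VAT calls, and changes over 4-fold 37 and 46. Of the genes called in both depots of sedentary rats, 155 were higher and 170 lower in both, against 11.9 and 14.5 for independent lists, and none was called in opposite directions. Among the SAT calls, 97.8% had the same sign in VAT, and fold changes correlated at r = 0.946 across these genes, which are not independent replicates. Over all genes tested in both depots r was 0.442, and 0.516 without the atypical libraries; the depots came from the same rats. A test of the difference in the phase effect between depots, added after seeing the data, called 0 genes with edgeR, with 843 at an unadjusted p under 0.05, 11 with DESeq2 and 74 with limma voom; without the 4 atypical libraries edgeR called 0, with 1257 at an unadjusted p under 0.05. Without the atypical pair the SAT count was 1241, with all 463 first calls among them, and the VAT count 2065. The atypical SAT libraries were in neither group compared here and entered this test only through the fit shared by the 4 groups. The lower SAT count thus does not show a weaker phase effect in SAT than in VAT. DESeq2 called 772 in SAT, and limma voom 2849 in SAT and 2398 in VAT. A fit of the 2 SAT groups alone called 1671, and the number of detected genes as a covariate gave 2467 in VAT. The first principal component as a covariate gave 773 and 4072, but in VAT this component largely followed phase. The SAT count fell to 290, 264, 292 and 292 when early control replicate 2, early control replicate 6, late control replicate 1 or late control replicate 4 was left out.

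In exercised rats the same comparison, late against early exercise, gave many of the same genes. ENSRNOG00000013408 stood at 1.74 ± 0.717 CPM early and 58.7 ± 22.9 CPM late in SAT, and at 2.56 ± 0.459 and 77.4 ± 16.6 CPM in VAT (SD, n = 6). ENSRNOG00000009329 fell from 92 ± 23.6 to 3.66 ± 0.553 CPM in SAT and from 77.7 ± 22.3 to 2.69 ± 1.37 CPM in VAT. In SAT 1413 genes were higher and 1079 lower at the late phase, and in VAT 1426 were higher and 1493 lower. Of the genes called in sedentary rats, 113 higher and 167 lower in SAT were called again in the same direction, against 21.6 and 18.2 for independent lists. In VAT 525 and 583 were called again, against 76.8 and 88.9. Across the sedentary calls, 96.8% in SAT and 97.5% in VAT kept their sign in exercised rats, with r = 0.918 and 0.859 across genes. Between the depots of exercised rats, 338 genes were called higher and 494 lower in both, against 140 and 115 for independent lists, and 40 were called in opposite directions. Among the SAT calls 70.3% had the same sign in VAT, with r = -0.0574 across these genes and 0.00705 across all genes. Without the atypical libraries 482 and 499 were shared, 6 were opposite, 90.2% of the SAT calls had the same sign, and r was 0.805 across the SAT calls and 0.453 across all genes. Without the atypical pair the SAT counts were 874 higher and 889 lower, and those in VAT 1532 and 1872; leaving out SAT late exercise replicate 6 alone gave 1500 in all, a fit of the 2 SAT groups alone gave 383, limma voom 1339 in SAT, and the first principal component as a covariate 1168 in SAT and 4583 in VAT.

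A set of genes was called for phase in both depots and under both activities, with 79 higher and 119 lower at the late phase among 13755 genes tested in both depots. Independent lists would share 0.12 in each direction. Of this set 23 of the genes that rose and 42 of those that fell changed over 2-fold in all 4 comparisons, and 5 and 11 changed over 4-fold. Without the atypical libraries 198 were higher and 218 lower in all 4 comparisons, of which 76 and 112 were in the first set. None of the 4 IDs above passed the threshold between exercised and sedentary rats at either phase in either depot, which does not exclude a difference. The largest fitted difference was a log2 change of 0.904 ± 0.431 (SE) for ENSRNOG00000042717 in SAT at the late phase. It stood there at 0.33 CPM in sedentary and 0.615 CPM in exercised rats (adjusted p = 0.158, edgeR). Over all tested genes, the phase effects with and without exercise, which share no library, correlated at r = 0.689 in VAT and at r = -0.0256 in SAT, and without the atypical pair at r = 0.568 in VAT (0.627 over the same genes) and at r = 0.348 in SAT (0.34). The covariances were 0.158 in VAT and -0.0107 in SAT. Over the same genes, leaving out 1 library moved r between 0.535 (without early control replicate 5) and 0.719 (without late control replicate 4) in VAT. In SAT it moved between -0.152 (without early exercise replicate 2) and 0.12 (without early control replicate 5). The jackknife standard errors were 0.197 in VAT and 0.283 in SAT, taken from left-out fits over the genes each of them tested.

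Exercise at the early active phase left no gene past the threshold in either depot. In SAT 0 of 14372 genes were called by edgeR, 3 by DESeq2 and 0 by limma voom. With edgeR 131 genes were at an unadjusted p under 0.05, where 719 would be expected by chance. Other splits of the same libraries gave a median of 193, also below 719, so the edgeR test was strict for these libraries. In VAT 0 of 13883 were called, with 345 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom. On simulated counts edgeR recovered 80.3% of 4-fold, 55.2% of 2-fold and 31.3% of 1.5-fold changes for this SAT comparison. For this VAT comparison it recovered 95.5%, 86.6% and 61.2%. The simulation gave each gene the same dispersion in all 4 groups and held no atypical library, so recovery in the real libraries may differ. Leaving out the atypical pairs, or any library of the compared groups, kept the edgeR count at 0 in both depots.

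For exercise at the late active phase in SAT, the calls depended on the fit. A fit of the 2 groups compared called 0 genes, while the fit of all 4 groups, which shares its spread among them, called many. Here 1126 genes were higher and 528 lower in late exercise than in late control (edgeR, adjusted p under 0.05), and 289 of them differed over 4-fold. The gene with the largest rise among those at 5 CPM or more went from 0.0397 ± 0.0971 to 7.28 ± 10.5 CPM (SD, n = 6; adjusted p = 0.0228, edgeR), with values from 0 to 26.3 CPM among the exercised rats. The largest fall went from 21.5 ± 9.8 to 6.14 ± 3.97 CPM (adjusted p = 0.0226, edgeR). Both atypical SAT libraries belonged to the exercised group. Of the 285 genes that rose over 4-fold, 284 were raised over 4-fold in both of these libraries, against the median of the other 22 SAT libraries. Without them 209 genes were higher and 101 lower, of which 170 were among the first calls, and neither of the above 2 genes passed the threshold (adjusted p = 0.142 and 0.1, edgeR). The log2 change of the first went from 7.19 ± 1.82 to 4.57 ± 1.73 (SE), and that of the second from -1.81 ± 0.454 to -1.51 ± 0.503. Of the 1654 calls 1604 kept their direction, and their median absolute log2 change went from 0.649 to 0.359. The count also moved with other single libraries, to 354, 352, 329 and 1076 without late control replicate 1, 2, 3 or 6, to 257 and 380 without late exercise replicate 4 or 6, and to 2904 and 3067 without late exercise replicate 2 or 5. A fit of the 2 groups alone called 0 genes, with 2982 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0947, DESeq2 called 2718, limma voom 298 and a fit with the replicate number as a block 385, and a covariate gave 3249 (number of detected genes) or 20 (first principal component).

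In VAT exercise at the late active phase left 0 genes past the threshold with edgeR, with 1557 at an unadjusted p under 0.05 where 694 would be expected by chance and a smallest adjusted p of 0.125. DESeq2 called 43 genes and limma voom with sample quality weights 200. Leaving out late exercise replicate 6 gave 36 genes with edgeR, and leaving out any other library of the 2 groups gave 0. Without the atypical pair edgeR called 0, with 2040 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0591. The gene with the smallest p among those that were higher stood at 8.24 ± 0.809 CPM in late control and 12.1 ± 1.77 CPM in late exercise (SD, n = 6; adjusted p = 0.125, edgeR).

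**Figure D4:**
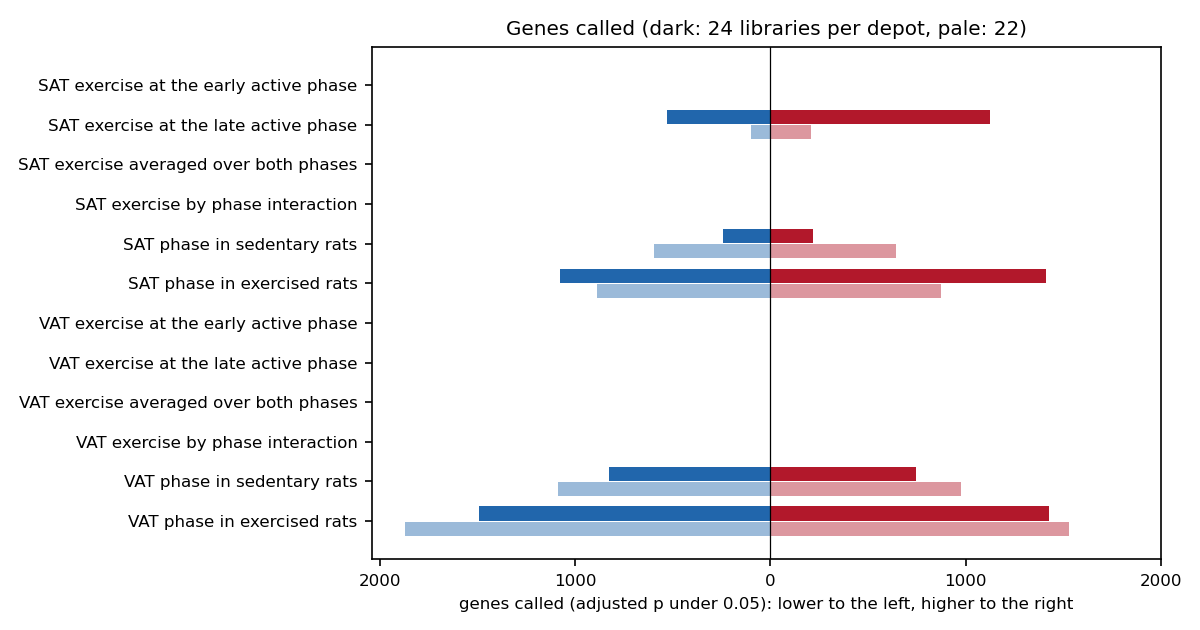
Number of genes called (adjusted p under 0.05, edgeR) in each comparison within a depot, with genes that were lower drawn to the left and genes that were higher to the right. Dark bars use all libraries and pale bars leave out the atypical pair of the depot; SAT exercise at the late active phase goes from 1654 to 310 genes, and the other exercise comparisons have at most 4.

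Whether exercise acted differently at the 2 phases was tested as an interaction. No gene passed in SAT (0 of 14372 with edgeR, 2411 at an unadjusted p under 0.05, smallest adjusted p of 0.114), where DESeq2 called 184 and limma voom 1. None passed in VAT (0 of 13883 with edgeR, 975 at an unadjusted p under 0.05), where DESeq2 called 2 and limma voom 0. Without the atypical pair the SAT interaction had 3 genes higher and 1 lower, and without late exercise replicate 5 it had 37. The gene with the smallest p among those with a lower interaction in SAT stood at 27.6 ± 1.71, 29.1 ± 1.3, 31.2 ± 1.32 and 20.7 ± 3.51 CPM in early control, early exercise, late control and late exercise (SD, n = 6; adjusted p = 0.114 with all libraries and 0.0497 without the atypical pair, edgeR). Averaged over both phases, exercise left 0 genes past the threshold in SAT (2342 at an unadjusted p under 0.05, 290 with DESeq2, 0 with limma voom) and 0 in VAT (785 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma voom). Without the atypical pairs these averages had 0 calls with edgeR, with 2072 and 1080 genes at an unadjusted p under 0.05. Fold changes of exercise at the early and late phases, which share no library, correlated across genes at r = -0.204 in SAT (covariance -0.0515) and at r = -0.0172 in VAT (covariance -0.00121). The SAT value had a jackknife standard error of 0.426, and lay at -0.378 without early exercise replicate 2, at 0.107 without early control replicate 5 and at -0.0101 without the atypical pair.

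The depots themselves differed in many genes. In sedentary rats 3177 of 14693 tested genes were higher in VAT and 3184 were higher in SAT (edgeR, adjusted p under 0.05), which was 43.3% of those tested. The differences were over 2-fold for 356 genes higher in VAT and 715 higher in SAT, and over 4-fold for 337 in all. With the rat as a block the count was 6469, of which 6065 were among the 6361 first calls, and without the 4 atypical libraries it was 7867. Whether exercise changed the depots differently was also tested. At the early phase 0 genes were called with edgeR (157 at an unadjusted p under 0.05, 5 with DESeq2, 0 with limma voom), and at the late phase 0 (2464 at an unadjusted p under 0.05, 172 with DESeq2, 0 with limma voom). Without the 4 atypical libraries the late-phase test had 0 calls and 1177 genes at an unadjusted p under 0.05.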

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

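Tests of the atypical libraries, of the number of detected genes and of the raised genes were chosen after their results were seen; the counts over other splits, the test of the changes over 4-fold and the tests of a like change in both depots were set before. The 8 groups of 6 libraries were each tested in 7 measures: library total, detected genes, genes over 4-fold above the depot median and the CPM of the 4 named IDs. Of these 56 tests 11 found a library far from the others, where chance alone gives about 1 in 20 groups, but they fell on 7 libraries and the measures are not independent. Detected genes stood out in SAT early exercise replicate 1 with 14653, in VAT early control replicate 5 with 16864 and in VAT early exercise replicate 3 with 17034. Genes over 4-fold above the depot median stood out in SAT late control replicate 6 (156), VAT early control replicate 5 (285), VAT early exercise replicate 3 (348) and VAT late control replicate 4 (79). ENSRNOG00000014448 stood at 6 CPM in VAT early control replicate 5 and at 5.27 CPM in VAT early exercise replicate 3, above the other early VAT libraries. ENSRNOG00000009329 stood at 5.36 CPM in VAT late exercise replicate 5 and ENSRNOG00000013408 at 3.11 CPM in SAT early exercise replicate 2.

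For exercise at the late active phase in SAT 1654 genes were called, as many in 2 of 100 splits of the 12 libraries. The highest other count was 2081. Chance is thus less likely but not excluded, given the many comparisons. A split that calls more genes points to a structure of the samples. Without the atypical pair 310 genes were called, as many in 4 of 100 splits of the remaining libraries (highest other count 1237). This argues only weakly against the pair as the whole cause: its removal was chosen after seeing the data, and another split called more. The pair may be the source of the large changes, since 14.5% of the 289 calls over 4-fold stayed over 4-fold without it. Whether the loss of calls is special to this pair stays open: the 6 pairs among the 4 other late exercise libraries gave 2966 to 4519 when left out, but late control replicates 1, 2 and 3, left out singly, gave 354, 352 and 329. The number of detected genes as a covariate kept 98.7% of the calls. The group means were close (16132 in late exercise, 16240 in late control), so it could take up little of a group difference. Late exercise replicates 1, 3 and 5 had 15411, 15443 and 15458 detected genes, against 16975 and 17180 in the atypical pair. The test thus cannot decide whether detection is a cause, in particular without the pair. The first principal component as a covariate left 20 genes. Exercise and handling of the groups stay open.

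A set of 799 genes was raised over 4-fold in both SAT late exercise replicates 4 and 6, where it took 21.9% and 14.1% of normalised counts against 0.4% to 6.04% in the other SAT libraries, while the 100 most abundant genes fell by a median of 1.79 and 1.82 on the log2 scale. Raised genes were counted here against the median of the 22 SAT libraries that were not atypical. Replicate 4 thus had 915 raised genes, where 879 lay over 4-fold above the median of all SAT libraries. Of these 915 genes, 87.3% were raised in replicate 6. In the other libraries the median was 1.9% and the highest 34.6%, in sedentary early control replicate 5. This overlap goes with a second profile of RNA in both replicates. The log2 excess CPM of the 799 genes correlated at r = 0.958 between them. As these genes were chosen as raised in both, this r adds no separate support. Exercise as a source stays open: of the 4 other late exercise libraries 1 had a mean log2 excess over 1 (1.33, 0.722, 0.386 and -0.143), against at most 0.024 in 5 late controls and 0.889 in the other, but sedentary early control replicates 5 and 6 had 1.96 and 1.48 and early exercise replicates 2 and 6 had 1.47 and 1.2. For the 523 of these genes that were also tested in VAT, the VAT libraries of these rats had an excess of at most 0.14. This argues against a change of those genes in both depots. Rat 6 matched its own VAT library (r = 0.633, against 0.503 with the best other), and for rat 4, which did not (0.0927 against 0.352), no late VAT library exceeded 0.294. The other genes of the set were not examined in VAT. Whether the profile came from another tissue in the dissected piece or a change of its cells stays open, as the IDs carry no names.

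In VAT 255 genes were raised over 4-fold in both early exercise replicate 3 and early control replicate 5, against the median of the 22 VAT libraries that were not atypical. Among the first library's raised genes 68.4% were raised in the second. The log2 excess CPM of the 255 genes, chosen as raised in both, correlated at r = 0.973 between these libraries. Of these rats 1 was sedentary and 0 of the 5 other early exercise libraries had a mean log2 excess over 1, which argues against exercise. Of the 248 VAT genes also tested in SAT, 222 belonged to the SAT set of 523, against 9.43 for independent lists, so the profiles of the depots may have a part in common. The SAT libraries of the same rats, which matched their VAT libraries (r = 0.533 and 0.945, against 0.326 and 0.39 with the best other), had an excess of -0.26 and 0.43 for the VAT genes, which argues against a change of these genes in both depots. It stays open for other genes of the SAT set in early control rat 5. Over the 523 genes its SAT and VAT libraries had 1.14 and 1.75 (1.98 in VAT early exercise replicate 3). They had 0.427 and 3.14 for the 222 shared genes and 1.66 and 0.726 for the 301 others. Across these 301 genes, however, the log2 excesses of its 2 libraries correlated at r = -0.383. Early exercise rat 3 had -0.228 in SAT and 0.876 in VAT for them.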

How the results depend on the processing

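Leaving out the atypical libraries, both covariates and the correlations over a fixed set of genes were chosen after seeing the data. The 4 named IDs kept their direction and stayed past the threshold under all 21 settings in each of the 4 phase comparisons. The DESeq2 size factors and the removal of the low-count filter left every count of calls within 1.5 times of the reported one; without the filter the VAT correlation of phase effects went from 0.689 to 0.44. Fits with 1 library left out tested 13942 to 14003 VAT genes in place of 13883 and gave 0.473 to 0.657. Over the first 13883 genes the fits without early control replicate 5 and early exercise replicate 3 gave 0.535 and 0.539, and those without any other library 0.659 to 0.719, so leaving out either of these 2 libraries lowered r more than the added genes did. The DESeq2 Wald test gave 3 genes for SAT early exercise, 2718 for SAT late exercise, 290 for the SAT average, 184 for the SAT interaction, 772 for SAT phase in sedentary rats, 43, 1 and 2 for VAT late exercise, average and interaction, and 5, 172 and 11 for the depot interactions with early exercise, late exercise and phase. Voom with quality weights gave 298 for SAT late exercise, 1 for the SAT interaction, 2849 and 1339 for SAT phase in sedentary and exercised rats, 200 for VAT late exercise, 2398 for VAT phase in sedentary rats and 74 for the depot by phase interaction. With only the 2 groups compared, SAT late exercise gave 0 and SAT phase 1671 in sedentary and 383 in exercised rats. The number of detected genes as a covariate gave 3249 for SAT late exercise, 24 for the SAT average, 1 for VAT late exercise and 2467 for VAT phase in sedentary rats. The first principal component as a covariate gave 20, 2, 1, 773 and 1168 for SAT late exercise, average, interaction, phase in sedentary and phase in exercised rats, and 3, 4072 and 4583 for VAT late exercise and the VAT phase comparisons. In VAT this component came from the same data and largely followed phase, so its counts there cannot serve as a check of the phase effect. Without the atypical pair SAT late exercise gave 310, the SAT interaction 4, SAT phase in sedentary rats 1241 and the SAT correlation of phase effects 0.348. For SAT phase in sedentary rats the atypical pair was in neither compared group and acted only through the shared fit. The cause of the other differences was not tested.

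Left out in turn, single libraries moved SAT late exercise from 257 to 3067, the SAT average from 0 to 4, the SAT interaction from 0 to 37, SAT phase from 264 to 463 in sedentary and from 1500 to 3410 in exercised rats, VAT late exercise from 0 to 36, and VAT phase from 1236 to 1587 and from 2371 to 3053; early exercise in both depots and the VAT average and interaction stayed at 0. The average rose to 4 and 1 without SAT late exercise replicate 2 or 5, and the interaction to 37, 4 and 1 without late exercise replicate 5, late exercise replicate 2 or early exercise replicate 1.

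With replicate number as a replicate block within a depot, SAT late exercise gave 385 genes, and no other count moved by over 1.5 times (372 and 1918 for SAT phase, 1519 and 2823 for VAT phase, 0 for the other exercise comparisons). These numbers name different rats: same-numbered libraries of different groups correlated at a mean r of 0.066 in SAT and 0.035 in VAT, and 3 and 6 of 24 libraries correlated best with their own number. The rat block between depots, where the numbers do pair the libraries, gave 6469 for the depot comparison and 0 for the depot interactions and changed no call count by over 1.5 times. The tests of the fixed gene lists, with estimated correlation, fry and block, and the settings for genes named by symbol were not run, since the IDs match no list. Depth limits the low end: a gene with 0 counts in the lowest library may have up to 0.228 CPM, and in the SAT early exercise simulation 31.3% of 1.5-fold changes were recovered.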

Other observations

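The tests of a like change in both depots and the counts over other splits were set before their results were seen, while leaving out the rats of the atypical SAT libraries and the depot by phase interaction were chosen after seeing the data. With all libraries, 78.4% of the SAT genes called for late exercise and also tested in VAT had the same sign there, with r = 0.309 and a slope of 0.0558 across these genes, against 95.5% and r = 0.763 without the atypical libraries. Of the SAT genes called without the atypical pair and also tested in VAT, 205 of 208 that were higher and 90 of 101 that were lower had the same sign in VAT, and 114 and 32 of them reached an unadjusted p under 0.05 there. Their median log2 change was 0.514 in SAT and 0.22 in VAT for the higher genes, and -0.467 and -0.154 for the lower. The depots come from the same rats, so this was tested by regrouping the rats, each with both depots.

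The hypothesis of a like change of expression in both depots was tested on mean differences of log2 CPM across 13755 genes. With all 12 late rats r was 0.264, and 29 of 462 splits gave an r as high (highest other 0.4), which does not exclude chance. Without the 2 rats r was 0.402, and 1 of 210 splits, the real one, gave an r as high (highest other 0.379). A shift of the daily rhythm or of the collection time may give the same picture; without the 4908 genes called for phase, r was 0.333 over 8847 genes, and again 1 of 210 splits gave an r as high (highest other 0.331, median 0.14). This does not exclude such a shift, because 8.96% to 18.6% of the genes left had an unadjusted p under 0.05 in each phase comparison, where 5% would by chance, and because the highest other split was close. Leaving out these rats was chosen after seeing the data, and the handling of the groups stays open, so a like response of both depots remains a hypothesis.

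Against other splits of the same libraries, with all counts as reported, the phase comparisons were exceeded by none: 1 of 100 splits, the real one, reached 463 in SAT sedentary (highest other 32), 2492 in SAT exercised (1777), 1575 in VAT sedentary (499) and 2919 in VAT exercised rats (1568), and likewise 6361 for the depot comparison (1919). Where no gene was called, the number at an unadjusted p under 0.05 was compared. VAT late exercise had 1557 genes in the real split, with 4 of 100 splits as large and a highest other of 1732. The depot by late exercise interaction had 2464 (4 of 100, highest other 3154). Without the 4 atypical libraries it had 1177, and no splits were drawn. The depot by phase interaction had 843 (3 of 100, highest other 905, median 198), where 735 would be expected by chance. Its splits mixed early and late rats and so removed the phase effect, so they cannot decide whether chance gave its count. Splits of the depot interactions were fitted without the rat block. For these late exercise tests chance was less likely but not excluded, given the many comparisons and the larger counts of other splits. It was not excluded for SAT early exercise (131, 81 of 100, highest other 893), the SAT average (2342, 5 of 100, highest other 2642), the SAT interaction (2411, 9 of 100, highest other 3281), VAT early exercise (345, 82 of 100, highest other 5102), the VAT average (785, 45 of 100, highest other 2532), the VAT interaction (975, 34 of 100, highest other 3048) and the depot by early exercise interaction (157, 85 of 100, highest other 1690). Among the other splits for VAT early exercise the most genes called was 3167, which points to a structure of the samples other than the groups.

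Of the 35 genes whose deviations from the group mean followed the rat in both depots, 6 were at 0 counts in both depots of at least 3 rats and over 1 CPM in both depots of at least 3 other rats. Of the 144 combinations of these 6 genes and 24 rats, 40 were at 0 in both depots and 70 were over 1 CPM in both. In 1 the gene was at 0 in a depot and over 1 CPM in the other, and the rest met none of these conditions. The genes were chosen for agreement between the depots, so the few opposite combinations follow largely from that choice.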
